A study of Mus musculus with 2 samples.

How the data were processed

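Total RNA was measured from bone marrow lineage- Sca1+ c-Kit+ cells of a control and an Ago2 Hem KO mouse sample of the C57BL/6J strain, 1 array each. Per the labels' protocols, RNA was extracted with a column kit, its quality was examined on a Bioanalyzer, and it was amplified and labelled with biotin for Illumina bead arrays. The labels do not say how many animals each sample pooled, and the groups are named as the labels name them.

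The deposited non-normalized table gives, per the file headers, a mean bead intensity on a linear scale for each probe and array, with no normalization between arrays. The same deposited table gives a detection p-value for each probe and array, whose steps match a comparison with 936 negative control probes. BeadStudio is named in the submitters' processing notes without a version. The authors also deposited a value table of intensity on a linear scale for the same arrays. Its columns share a single distribution (sorted values differed by at most 0.175, medians 86.2 and 86.2) and each ranks probes as that array's non-normalized signals do (Spearman 1.00). Its distribution lay below both arrays' signals at 99.998% of ranks, so it is not the mean of these 2 arrays, and the target distribution is not given in the sources used here. Its log2 was used only as an alternative, and its direction and sample order were settled by that rank comparison.

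From the non-normalized signals, the background mean and SD of each array were inferred from the detection p-values with limma 3.58.1 in R 4.3.3. They came to 84.7 and 4.20 for the control and 87.8 and 4.38 for the Ago2 Hem KO array. Signals were corrected with the normexp model, an offset of 16 was added, the arrays were quantile normalized, and log2 was taken. Quantile normalization forces both arrays to one distribution, so a change shared by most genes is removed, and the offset shrinks differences of dim probes towards 0. A probe counted as detected where its detection p was under 0.01. Differences are Ago2 Hem KO minus control on the log2 scale.

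Probes were named through the platform annotation given for them, and symbols were updated through the gene identifier with the RefSeq gene table of assembly GRCm38.p6, from which only symbols and gene spans were used. Of the probes, 34885 had 1 gene symbol, of which 34807 matched that table, 18 had several and 10378 had none. Probes with several symbols were not named. The value of a gene was that of its brightest probe, by mean log2 signal, among those detected on both arrays. For a gene detected on 1 array only, the fold is a lower bound, the bright value against the higher of the dim probe's own value and the lowest normalized value among detected probes of the dim array.

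With 1 array per genotype no test was run and no p-value across genes is given. Genes are said to rise or fall where they changed at least 2-fold, and lists where their median lay outside the central 95% of random lists. The named genes followed a rule set before the data were examined. It takes the Argonaute genes, the 12 largest rises and 12 largest falls at 2-fold or more whose detected probes all had the same sign, the 4 largest lower bounds per direction, and reference genes. Within each list it takes up to 4 members at 2-fold or more, or else the highest and the lowest member. Only 11 genes fell 2-fold. Further members and genes named beside these, among them the remaining 2-fold genes, Aqp1, other erythroid and neutrophil genes and mitochondrially encoded genes, were chosen after their values were seen.

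Gene lists numbered 32 and were set before the data were examined. A list's median was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and a list stood apart under the 2.5th or over the 97.5th percentile. Lists with fewer than 5 members detected on both arrays have their members' values only. Lists of plasma cell genes and of late erythroid genes were added after the data were examined. Gene families by symbol stem, with at least 10 detected members, were described in the same way.

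The alternatives were no background correction, an offset of 50, scaling to the same median, cyclic loess, the authors' value table, a detection p under 0.05, no filter on detection p, only detected probes above the median signal, the mean of a gene's detected probes, and random lists not matched on signal. Random lists matched on signal and gene span, and the lower bounds under other background and normalization settings, were added after the data were examined.

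The steps were tested on simulated arrays for the comparison of Ago2 Hem KO with control, with 200 changed genes and 8884 genes detected on both arrays. Of detected genes simulated at 4-fold, 100% were called at 2-fold or more, and 95.2% of those simulated at 0.25-fold. Of those simulated exactly at 2-fold or 0.5-fold, 36.7% and 29.2% passed, since the offset shrinks them below the threshold. None of the 8695 unchanged genes passed. Both simulated arrays were drawn from the control signals, with a spread taken from bright probes. They held no variation between animals, sorts or RNA preparations, so this gives no rate of false calls for the real arrays. Of 200 unchanged lists of 15 genes, 6.0% lay outside the central range, and of 50 lists shifted by 0.3 on the log2 scale, 100% lay above it. The analysis used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, with matplotlib 3.10.9 for the plots. The planned comparison of genes by microRNA seed matches was not run, because 3' UTR sequences were not used here.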

Results

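Gene expression was compared between bone marrow LSK cells of a control mouse sample and of an Ago2 Hem KO sample, both of the C57BL/6J strain. LSK cells lack surface markers of mature blood lineages and carry Sca1 and c-Kit, a gate that holds haematopoietic stem cells and early progenitors. Ago2 encodes an Argonaute protein, which binds microRNAs and with them silences messenger RNAs. The comparison asks how the transcripts of these cells differ when Ago2 is deficient. The labels give 1 sample per genotype, each on 1 Illumina bead array, so there are no replicates, no test was possible, and the number of arrays limits the precision of every value. Each array carried 45281 probes, of which 14834 (32.8%) were detected above background in the control and 15594 (34.4%) in the Ago2 Hem KO sample. Median signals were 88.1 and 91.7. Across the 14340 probes detected on both arrays, normalized signals correlated with r = 0.985, a correlation across probes, which are not independent replicates.

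The targeted gene, Ago2, was lower in the Ago2 Hem KO sample on each of its 3 probes. The brightest Ago2 probe fell 2.44-fold, from a signal of 288 to 180. The others were 1.73-fold lower (226 against 181) and 1.36-fold lower (106 against 103). Ago2 stayed above background on both arrays on all of these probes. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part checks nothing about the deletion. The difference of the brightest probe was under 2-fold in the authors' value table, at a log2 difference of -0.83, and at -0.88 without background correction, while the mean of the 3 probes gave -0.84. Ago1, Ago3 and Ago4, the other Argonaute genes, were not detected on either array.

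Of 8212 genes detected on both arrays, 25 rose and 11 fell at least 2-fold in the Ago2 Hem KO sample, and 96.2% lay within 1.5-fold. Genes of red cell formation were prominent among the rises. The α-globin gene Hba-a1 rose 4.39-fold, carbonic anhydrase 1 (Car1) 3.30-fold, the erythroid transcription factor gene Klf1 2.72-fold and the β-globin gene Hbb-bt 2.63-fold. The globin genes have near-identical copies, so which copy a globin probe measured is uncertain. Other rises were those of the secreted protein gene Igfbp7 (3.39-fold), the T cell receptor γ segment Trgv4 (3.13-fold), the amino acid transporter gene Slc38a5 (3.05-fold) and the ficolin gene Fcna (2.90-fold). The mitochondrial chaperonin gene Hspe1 rose 2.75-fold and Xist, the RNA that silences the inactive X chromosome, 2.74-fold. Pou2af1, a transcriptional coactivator of B lineage cells, rose 2.63-fold, and Mzb1, which encodes an endoplasmic reticulum protein of antibody-secreting and marginal zone B cells, rose 2.61-fold. Igfbp7, Trgv4 and Pou2af1 were barely above background in the control, at signals of 98.9, 98.2 and 99.5. Their Ago2 Hem KO signals were 191, 178 and 166, so their folds rest on the background correction.

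The genes that fell besides Ago2 did so by 2.00-fold to 2.84-fold. The carboxylesterase gene Ces1d fell 2.84-fold and the extracellular glutathione peroxidase gene Gpx3 2.77-fold. The inhibitory receptor gene Lag3 fell 2.39-fold, the matrix metalloproteinase gene Mmp2 2.29-fold and the mitochondrially encoded complex I gene ND5 2.28-fold. Retnlg and Ltf, both expressed in neutrophils, fell 2.17-fold and 2.00-fold. Zfp763, Cracr2b and the proteoglycan gene Bgn fell between 2.06-fold and 2.14-fold. Ces1d, Lag3 and Retnlg were near background in the Ago2 Hem KO sample, at signals of 104, 108 and 109 against 148, 143 and 137 in the control. The remaining 2-fold rises, from 2.05-fold to 2.57-fold, included the mitochondrially encoded cytochrome c oxidase subunit COX2 (not Ptgs2), the sphingosine kinase gene Sphk1 and the β-globin gene Hbb-bs.

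**Figure D1:**
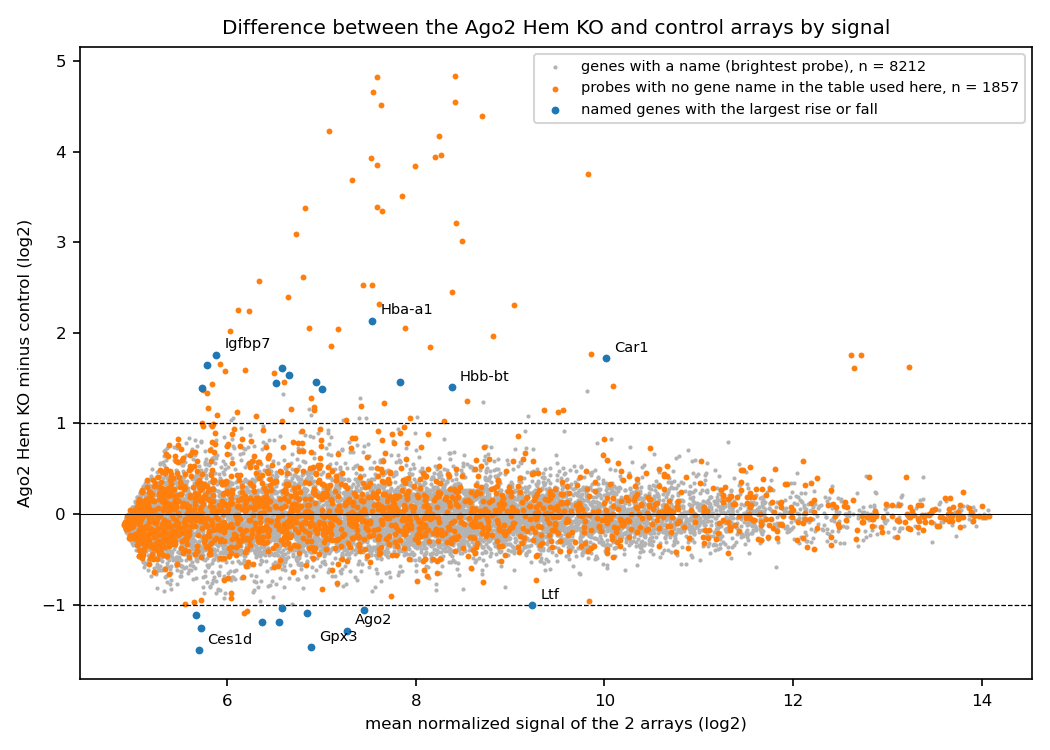
Each point gives the difference in normalized signal between the Ago2 Hem KO and control arrays (y axis, log2) against the mean of both arrays (x axis, log2), for 8212 named genes in grey and 1857 probes with no gene name in orange. Blue points are the named genes with the largest rises and falls, dashed lines mark 2-fold, and the orange points reach 28.7-fold while Hba-a1, the highest named gene, lies at 4.39-fold.

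**Figure D2:**
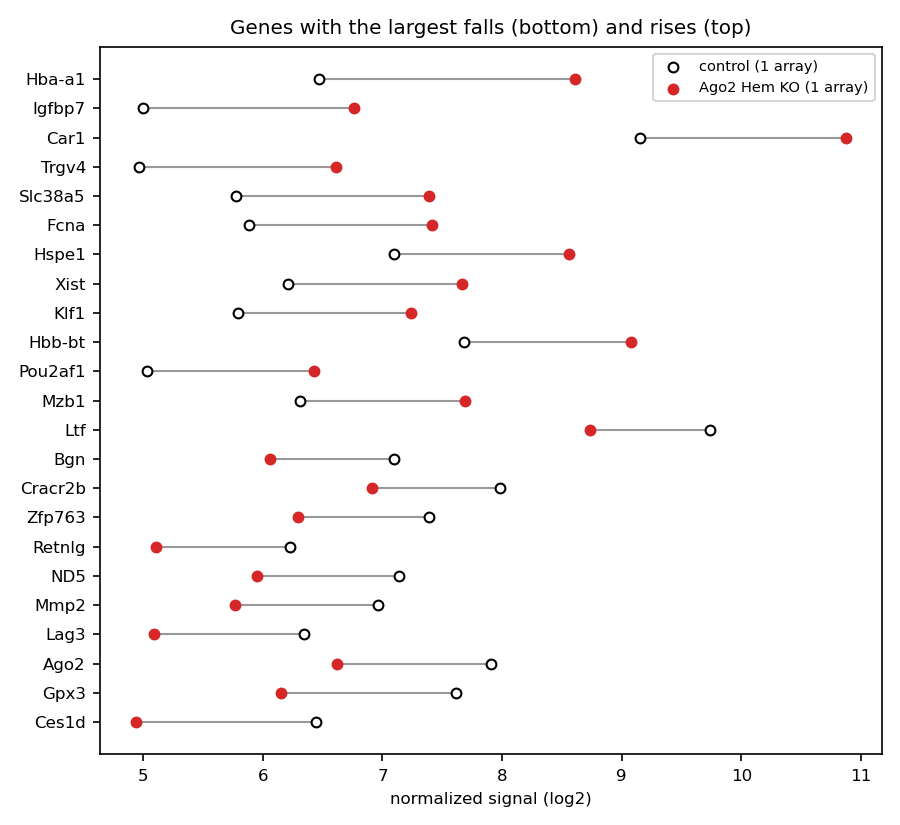
Normalized signal (x axis, log2) of the genes with the 12 largest rises and the 11 falls, in the control (open circles) and the Ago2 Hem KO sample (red circles), 1 array each. Car1 is the brightest of the genes that rose, with deposited signals of 594 and 2099, and Ltf the brightest of those that fell, with 853 and 533.

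The counts of 2-fold genes moved with the processing. In the authors' value table and without background correction, 6 genes rose and 0 fell, the rises being those of Hba-a1, Car1, Hspe1, Hbb-bt, Hbb-bs and COX2 in both. Scaling the arrays to the same median gave 60 rises and 4 falls in place of 25 and 11, and moved the median difference of all genes by 0.21 on the log2 scale. None of the other named genes with a 2-fold difference changed sign under any alternative that gave it a value. Over 3016 genes with a second detected probe, the second-brightest probe had the same sign as the brightest in 63.8%. Of 7 genes at 2-fold or more with a second probe, that probe had the same sign in 7 and reached 2-fold in 2.

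The erythroid genes rose as a group. The median log2 difference of the 12 detected members was 0.26, against -0.05 for random lists of the same size and signal, the 99.96th percentile of 10000 such lists, a description of these 2 arrays. Hba-a1, Car1, Klf1 and Hbb-bs rose at least 2-fold, 10 of the 12 lay above 0, and the lowest member was Icam4 at -0.31. The water channel gene Aqp1 differed by 0.67 on its brightest probe and by 1.06 and 0.93 on its other probes. The erythropoietin receptor gene Epor and the red cell membrane genes Slc4a1, Ermap, Rhag and Ank1 were detected in the Ago2 Hem KO sample only. Alas2, Rhd, Epb42 and Trim10, which are expressed late in red cell formation, were not detected on either array. The list lay above the central 95% range of random lists in all 12 settings tried, and its median was 0.95 with only detected probes above the median signal, where 6 members were left. Haem synthesis and iron genes lay at a median of 0.08, the 93.5th percentile, with Hmox1 highest at 0.65 and Alas1 lowest at -0.26.

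Oxidative phosphorylation genes also rose as a group, by a small amount. Their median was 0.09 over 30 detected members against -0.02 for matched random lists, the 99.82nd percentile, and 20 of the 30 lay above 0. No member reached 2-fold. The cytochrome c oxidase subunits Cox7a2 (0.98) and Cox6c (0.79) were highest, and the complex III subunit Uqcrc1 (-0.28) was lowest. The list lay above the range in all 12 settings. Among mitochondrially encoded genes, COX2 rose 2.57-fold and ND5 fell 2.28-fold, while CYTB, ND1 and ND4 differed by -0.01, 0.02 and 0.09.

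Among marker lists of other blood cells, B cell markers fell as a group, with a median of -0.31 over 7 detected members against -0.07 for matched lists, the 1.08th percentile. All 7 lay below 0, with the surrogate light chain gene Igll1 lowest at -0.79 and Vpreb3 highest at -0.03. This list was outside the range in 6 of 11 settings, and its percentile was 8.82 without background correction, 9.80 in the authors' value table, 5.12 with an offset of 50, 10.5 with no filter on detection p and 3.06 with random lists matched on gene span as well. Mature neutrophil markers lay at the 36.3rd percentile with a median of -0.07. Of the 11 detected, Retnlg and Ltf fell at least 2-fold and Mmp9 was detected in the control only, while S100a8 (-0.01) and Ngp (-0.05) differed little. Both of the latter were bright in control and Ago2 Hem KO alike, S100a8 at signals of 12721 and 13036 and Ngp at 1880 and 2113. Megakaryocyte and platelet genes had a median of 0.04, at the 87.0th percentile, with Pf4 highest at 0.58 and Gp1bb lowest at -0.51. Mast cell, basophil and eosinophil genes lay at the 94.6th percentile, from Mcpt8 at 0.46 to Hdc at -0.14.

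The remaining marker lists had fewer than 5 genes detected on both arrays. Of the monocyte and macrophage markers, the complement genes C1qa, C1qb and C1qc were detected in the Ago2 Hem KO sample only, while Cx3cr1 differed by 0.36 and Cd14 by -0.35. Dendritic cell markers ran from H2-Aa at 0.22 to H2-Eb1 at -0.64, and T and NK cell markers from Prf1 at 0.45 to Thy1 at -0.70. Stromal and endothelial markers were represented by Pdgfrb (0.19) and Emcn (-0.18), with 13 of 16 not detected on either array. Among the sex-linked genes, Xist differed by 1.45 on its brightest probe and by 0.11, 0.63 and 0.73 on the others, so that both samples gave Xist signal above background. The sex of the animals is not given in the sources used here, and the Xist difference cannot be separated from it. The Y-linked genes Eif2s3y and Uty were detected in both samples, with differences of 0.40 and -0.20, and Kdm5d in the Ago2 Hem KO sample only. Uty was called on probe ILMN_2907351 alone, near background at signals of 99.4 and 102 in control and Ago2 Hem KO. Eif2s3y was called on ILMN_1241001 alone, at 160 and 217, and Kdm5d at a signal of 104. Other probes of these genes were not detected on either array.

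Lists of stem and progenitor cell genes stayed within the range of matched random lists. Haematopoietic stem cell genes had a median of -0.17 at the 6.58th percentile, with the transcription factor gene Gata2 highest at 0.45 and Gprasp2 lowest at -0.65, and 11 of the 16 detected lay below 0. With only detected probes above the median signal, where 5 members were left, the same list lay at the 93.7th percentile. Lymphoid-primed progenitor genes had a median of 0.03 and a mean of -0.03, at the 79.7th percentile, from Mef2c at 0.15 to Dntt, which encodes terminal transferase, at -0.50. Myeloid progenitor genes had a median of -0.04 at the 41.0th percentile, from Csf3r at 0.48 to F13a1 at -0.57. They lay below the range under scaling to the same median (0.33) and cyclic loess (0.99). The detected Csf3r probes differed in sign. All 20 myeloid progenitor genes were detected on both arrays. Prtn3 and Elane had control signals of 15568 and 15309, against a highest signal of 17868.5 on that array. Of 25 stem cell genes on the array, 16 were detected on both arrays and 7, among them Procr, Hlf and Slamf1, on neither. The purity of the sorted cells was not tested. Hox and partner genes lay at the 94.96th percentile, from Hoxa5 at 0.39 to Hoxb2 at -0.27, and moved above the range in 3 of 11 settings.

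Among genes detected on both arrays, the machinery that acts with Argonaute proteins, and described microRNA targets in blood cells, contained none that changed 2-fold other than Ago2. Lin28a, listed with this machinery, was detected in the Ago2 Hem KO sample only. Small RNA and mRNA decay genes had a median of 0.07 over 22 detected members, at the 96.99th percentile, inside the range in these settings and above it in 4 of the 12. Cnot1, a scaffold of the deadenylase complex, was highest at 0.65 and the helicase gene Mov10 lowest at -0.43. The detected Cnot1 probes differed in sign. Described microRNA targets had a median of 0.00 over 21 detected members, at the 77.3rd percentile. Arid3a was highest at 0.50 and Bach1 lowest at -0.33. Another 10 listed targets, among them Hmga2 and Lin28b, were not detected on either array. A comparison of genes with and without microRNA seed matches in their 3' UTRs was not run, since no 3' UTR sequences were used here.

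**Figure D3:**
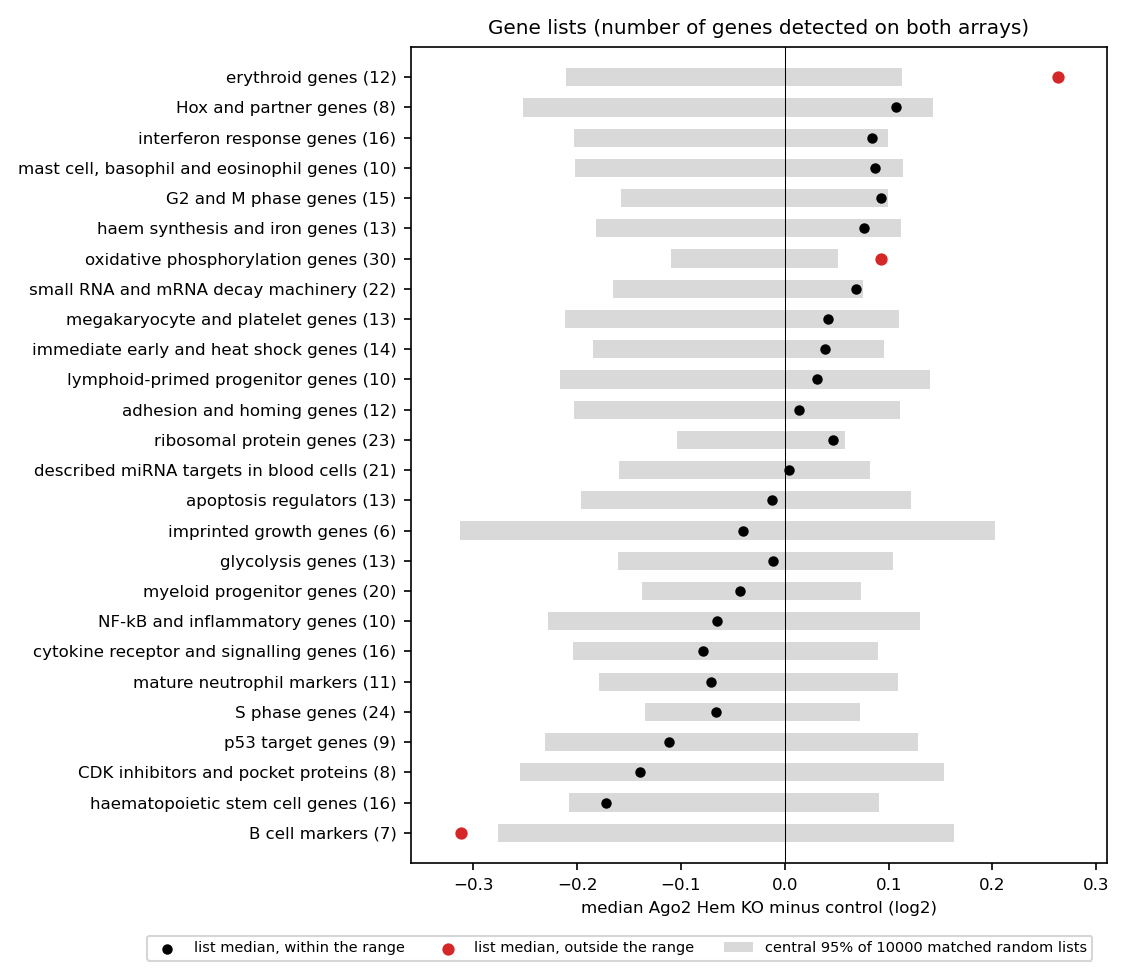
Median log2 difference (x axis, Ago2 Hem KO minus control) of the 26 gene lists with at least 5 genes detected on both arrays, with the number detected in parentheses. Grey bars give the central 95% of 10000 matched random lists, and red points mark the 3 lists outside it, erythroid and oxidative phosphorylation genes above at 0.26 and 0.09 and B cell markers below at -0.31.

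S phase genes lay at the 26.4th percentile, from Ccne2 at 0.38 to Ccne1 at -0.79, and G2 and M phase genes at the 96.8th, from Kif23 at 0.48 to Cenpa at -0.20, with the latter list above the range in 4 of 12 settings. CDK inhibitors and pocket proteins lay at the 22.8th percentile, from Rb1 at 0.39 to Cdkn1c at -0.45, and were above the range (97.9) with only detected probes above the median signal, where 5 members were left. For Kif23 and for Rb1 the detected probes differed in sign. Among stress and survival lists, p53 target genes lay at the 25.3rd percentile, from Cdkn1a at 0.33 to Tnfrsf10b at -0.56, and apoptosis regulators at the 61.5th, from Mcl1 at 0.23 to Diablo at -0.44. Interferon response genes lay at the 96.4th percentile, from Rsad2 at 0.33 to Ifit2 at -0.29, and were above the range in 3 of 12 settings. NF-kB and inflammatory genes lay at the 42.9th, from Nfkbiz at 0.29 to Irak2 at -0.33. Immediate early and heat shock genes lay at the 87.6th percentile, with Fosb, an AP-1 transcription factor gene, rising 2.06-fold.

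Among metabolic and signalling lists, ribosomal protein genes lay at the 95.7th percentile, from Rpl23 at 0.19 to Rpl22 at -0.42. Glycolysis genes had a median of -0.01 and a mean of 0.03 at the 59.4th percentile, from Pgk1 at 0.39 to Ldha at -0.32. Cytokine receptor and signalling genes lay at the 40.5th percentile, from Socs3 at 0.65 to Tek at -0.62. Adhesion and homing genes lay at the 78.6th, from Cd34 at 0.30 to Esam at -0.57. Imprinted growth genes had a median of -0.04 and a mean of 0.01 at the 58.1st percentile, and their member Dlk1, a Notch family ligand gene, rose 2.09-fold. In total 3 of 26 lists lay outside the range, where 1.3 would by chance if genes varied independently. Genes of a list can vary together and some lists share members, so that number is only a rough guide. As reference genes, Actb differed by -0.31, Gapdh by -0.07 and Hprt by 0.07 on their brightest probes, the 4 Actb probes differing in sign. The other Hprt probes differed by 0.50 and 0.69, and Ptprc was detected in the Ago2 Hem KO sample only.

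Genes detected in the Ago2 Hem KO sample alone numbered 440 and in the control alone 228. Detection was called on signals not yet normalized, and the Ago2 Hem KO array was brighter, with a 75th percentile signal of 135 against 121, which bears on every gene given here as detected in 1 sample only. For these only a lower bound of the fold can be given. The collagen gene Col5a1 was at least 3.37-fold higher in the Ago2 Hem KO sample, the complement genes C1qc and C1qb at least 2.94-fold and 2.75-fold, and the Na,K-ATPase subunit gene Atp1b2 at least 2.11-fold. In the other direction, Rhbdf1 was at least 2.05-fold higher in the control, the complement gene C4b at least 1.95-fold, and Rasl12 and Fkbp1b at least 1.76-fold. All 8 had signals under 190 on the array that detected them, and the bounds rest on the background correction: without it 0 of the 8 reached 2-fold, with Col5a1 at 1.72-fold and Rhbdf1 at 1.30-fold.

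The largest differences lay in probes with no gene name in the annotation used here. Of 1857 such probes detected on both arrays, 72 (3.88%) rose at least 2-fold and 2 fell, against 43 of 12478 named probes (0.345%) that rose. Among them 22 rose at least 8-fold and 8 at least 16-fold, while 0 named probes rose 8-fold. Probe ILMN_1249975 rose 28.7-fold, from a signal of 127 to 2042, and ILMN_2499056 rose 28.4-fold, from 102 to 1176. Some were bright in the control already: ILMN_2704562 rose 3.39-fold, from 3426 to 12802, and ILMN_2684370 3.09-fold, from 5104 to 16768. The falls were those of ILMN_2632262 (2.13-fold) and ILMN_2770066 (2.11-fold). Another 355 unnamed probes were detected in the Ago2 Hem KO sample only, 59 of them at least 2-fold higher by their lower bound, and 104 in the control only. The highest of these bounds was at least 76.8-fold, for a probe with a signal of 97.4 in the control, not detected there, and 2613 in the Ago2 Hem KO sample. Without background correction that bound was 24.1-fold, and 25 of these probes were at least 2-fold higher. This group of probes was singled out after its values were seen, and its genes are not named here.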

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

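The counts of unnamed probes, the lower bounds of genes detected on 1 array only, and the matching on gene span were examined under alternatives chosen after the data were seen. The direction of Ago2 was the same in every setting that gave it a value, but its difference was under 2-fold without background correction (-0.88), in the authors' value table (-0.83) and with the mean of its probes (-0.84). Genes at least 2-fold higher and lower numbered 25 and 11, and became 6 and 0 without background correction, 15 and 2 with an offset of 50, 60 and 4 with scaling to the same median, 6 and 0 in the authors' value table and 11 and 2 with only detected probes above the median signal. Unnamed probes at least 2-fold higher numbered 72, and 46 in the authors' value table, 149 with no filter on detection p and 40 with only detected probes above the median signal, and those lower numbered 2, and 0 without background correction, with an offset of 50, with scaling to the same median, in the authors' value table and above the median signal. The smaller counts without background correction and with the larger offset follow from their construction, since both add a constant that shrinks differences of dim probes. The authors' value table had a median of 86.2 on each array, near the background means of 84.7 and 87.8, so it appears to keep the background too. The cause of the other changes in these counts was not tested. At a detection p under 0.05, genes detected on 1 array only rose from 668 to 1157, with 704 in the Ago2 Hem KO sample and 453 in the control. The share of genes whose second probe had the same sign was 63.8%, and 74.5% with scaling to the same median, 54.9% with no filter and 66.9% above the median signal. Lists outside the range numbered 3, and 5 with scaling to the same median, 6 at a detection p under 0.05, 6 with no filter and 5 with the mean of probes. Of 35 named genes at 2-fold besides Ago2, 29 were under 2-fold without background correction or in the authors' value table, 19 with an offset of 50, 7 with scaling to the same median, 4 with the mean of probes and 2 with cyclic loess, and 0 were reversed. Genes near background are the least certain: the background SD was 4.20 and 4.38 in signal, against median signals of 88.1 and 91.7. Of 8 named lower bounds, 5 were at least 2-fold, and 4 with cyclic loess or scaling to the same median, 1 with an offset of 50 and 0 without background correction or in the authors' value table. The comparison by microRNA seed matches and its alternatives were not run. No paired analysis was possible because each group held 1 sample.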

Other observations

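The plasma cell and late erythroid lists were added after the data were seen. The tests of B cells, of a lower share of sorted cells, of late erythroid cells, of plasma-restricted genes and of the share of unnamed probes in the deposited signals were chosen only after the result was seen. The plasma cell list had 11 detected members, of which 9 lay above 0, with a median of 0.16 at the 99.4th percentile. The endoplasmic reticulum chaperone gene Hsp90b1 differed by 0.80, the signal peptidase gene Sec11c by 0.67 and Creld2 by 0.59, while Xbp1 differed by -0.18 and Tnfrsf13b by -0.27. Mzb1 and Pou2af1 had been left out of this list because they had risen, no member reached 2-fold, and the list fell inside the range with the mean of probes, at the 97.0th percentile.

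Of 82 gene families grouped by symbol stem, 4 lay above and 2 below the range, where 4.1 would lie outside by chance if genes varied independently. Those above were the complex I subunits Ndufa (99.8th percentile), the mitochondrial import genes Timm (99.4), the ubiquitin pathway genes Ube (99.4) and the ATPase and ATP synthase genes Atp (98.2). Those below were Vps (2.15), genes of endosomal sorting, and Pik (2.28), phosphoinositide kinase genes.

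The rise of unnamed probes was weighed together with that of Mzb1 and Pou2af1, though nothing measured here ties these probes to those genes. In the deposited signals, before any correction, Mzb1 went from 141 to 298 and Pou2af1 from 99.5 to 166, the latter under 2-fold. Of all unnamed probes detected on both arrays, 55 (2.96%) were at least 2-fold and 24 at least 4-fold higher there. Of the named probes, 25 (0.200%) and 0 were. The 2-fold share of unnamed probes was 14.8 times that of named probes, with median ratios of 1.13 and 1.11. This argues against background correction and normalization as the whole cause of the excess among unnamed probes. Of the 74 probes at 2-fold after processing, 56 (75.7%) were at 2-fold in the deposited signals, which leaves processing open for the others. For B cells as a source, the B cell markers lay at the 1.08th percentile, though only some settings placed that list outside the range. None of the 7 detected markers lay above 0, which argues against more RNA of B lineage cells that express them. Pax5, Ms4a1, Cd22 and Blk were not detected on either array, so a small share of mature B cells stays open. RNA of plasma cells, which a sort on lineage markers, Sca1 and c-Kit is meant to exclude, is a candidate source for some of the probes. Whether the unnamed probes share a source was not tested. Some, such as ILMN_2684370 (5104 in the control, 16768 in the Ago2 Hem KO sample), were bright in the control already. The plasma cell list without Mzb1 and Pou2af1 lay at the 99.4th percentile, in a test written before its result was seen. The list itself was drawn up after the gene values were seen. Its higher members include the chaperone gene Hsp90b1 and the signal peptidase gene Sec11c, which are not restricted to plasma cells, while Xbp1 and Tnfrsf13b lay below 0. Its percentile therefore cannot tell plasma cell RNA from a difference in such general genes. Of 6 genes most restricted to plasma cells (Jchain, Sdc1, Tnfrsf17, Prdm1, Irf4 and Derl3) 0.0% were detected on the Ago2 Hem KO array, a check added after that result was seen, so plasma cell RNA stays open, as does an untested effect of the genotype.

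The rise of erythroid genes was weighed next. Its lowest percentile over the alternatives set beforehand was 99.92, which argues against background correction, normalization or the filter on dim probes as the whole cause. The test of a lower share of the sorted cells took it to raise the marker list of every other cell type. B cell markers lay at the 1.08th percentile, though outside the range in 6 of 11 settings only. That cannot decide the question, since cells of only some types would raise only their own markers. Among other markers, C1qa, C1qb and C1qc were detected in the Ago2 Hem KO sample only. Mature neutrophil markers lay at the 36.3rd percentile, and some, such as S100a8, were bright on both arrays. A sort for lineage-negative Sca1+ c-Kit+ cells is meant to exclude late erythroid cells. Their presence in the Ago2 Hem KO sample cannot be told apart from a change within progenitors. Of 6 late erythroid genes on the array, 3 (50%) were detected in that sample. In the control 1 was, which differed by -0.13, and dim probes leave the others undecided. A difference due to Ago2 may equally account for the rise of erythroid genes and was not tested, since genotype and sample are the same with 1 array each.

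The small rise of oxidative phosphorylation genes was weighed last. The lowest percentile over the alternatives set beforehand was 99.57 (scaling to the same median), which argues against normalization and filtering as its whole cause. These genes are short, with a median gene span of 7838.5 bases against 21004 for all detected genes, but with random lists matched on gene span too the list lay at the 99.82nd percentile, and gene span is not transcript length. A biological origin is a hypothesis only: genotype, cell composition and RNA quality may each account for it, and none was tested with 1 array per genotype.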
